A study of Mus musculus with 4 samples.

How the data were processed

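Single-stranded DNA sequencing (ssDNA-seq) was used in 2 lines of mouse embryonic stem (ES) cells grown on feeder cells. The Cdx2 ES line (MC1) carries a Tet-inducible, Flag-tagged copy of Cdx2, a homeobox transcription factor of the trophoblast, and its medium held 2 µg/ml doxycycline. Whether doxycycline turned this copy on or kept it off is not given in the sources used here, so no value here is read as an effect of Cdx2. The TT2 ES line is wild type. Per the labels' protocols, live cells were exposed to 100 mM potassium permanganate, which oxidises unpaired thymines and so keeps open DNA from closing again. Free 3′ ends were blocked with cordycepin triphosphate by terminal transferase. S1 nuclease then cut the single-stranded DNA, and the new 3′ ends carried biotin. After sonication to fragments of 200 to 700 bp, biotinylated fragments were captured on streptavidin beads and sequenced. Each line had 1 ssDNA-seq library and 1 input library, 4 libraries in all. There were no replicates, so every comparison of lines is a comparison of these libraries, and no p-value here is taken across samples.

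The deposited data used here were 5 lists of islands, the enriched intervals that a peak caller joins from windows along the genome. Bowtie2 2.3.1, Picard 2.9.0, SICER 1.1 and the genome build mm9 are named in the submitters' processing notes, without roles or order. Each line had a list with a window of 200 bp and a gap of 600 bp and a list of the same window and gap marked by the authors as unique mapping. The Cdx2 ES line had a further list with a window of 100 bp and a gap of 200 bp. Filters, duplicate removal and library totals were not given in the sources used here. Per the labels, each list held the raw count of ssDNA-seq reads and of input reads per island, for 1 ssDNA-seq library over its own input and with no pooling.

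Each list also held a p-value, an adjusted p-value (FDR) and a fold per island, deposited by the authors. The highest deposited FDR was 0.00999, so islands above 0.01 were not in the lists. The deposited fold was checked against the read counts. It was the ratio of ssDNA-seq to input reads divided by a single constant per list, 1.96 for Cdx2 ES and 3.57 for TT2 ES. Where an island held no input read, the authors' ratio used 0.25 in its place, which applied to 8 Cdx2 ES islands and 1 TT2 ES island. The fold is the authors' own value and was used within a list to describe, rank or filter islands. Where the folds of both lines were set side by side, the 4 read counts and the 2 constants were used. A fold against no input reads was recomputed against a floor of 3 reads and is given as a lower bound.

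The islands held 12087575 ssDNA-seq reads and 3854962 input reads in Cdx2 ES, and 6975557 and 1630722 in TT2 ES. The median island held 288 ssDNA-seq and 87 input reads in Cdx2 ES and 472 and 104 in TT2 ES, so the input reads limited the precision of a fold. Shares carry 95% exact (Clopper-Pearson) binomial intervals, and folds carry 95% intervals from the read counts. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules. For ratios between lines the interval was a normal approximation on the log counts of all 4 libraries.

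Islands were placed on the mm9 sequence with the GENCODE M1 annotation, and all positions are 1-based. Every island end on chromosomes 1 to 19, X and Y lay inside the reference sequence. The 105 Cdx2 ES and 52 TT2 ES islands on unplaced or unlocalised sequences were counted but not annotated. Shares of islands over promoters (1 kb to each side of a transcription start), untranslated regions, coding exons, introns and intergenic sequence were set against 1000 circular shifts of the list along each chromosome. The smallest p that these shifts can give is 0.000999. Shifted islands keep their number, widths and spacing. Overlap of lists was tested in the same way, with 1 shared base as the minimum. Clustering was tested against 1000 random placements, because shifting a list leaves its own spacing as it was. Correlations of log2 fold across shared pairs used 100000 resamples of the pairings. Islands are not independent replicates, and these tests describe positions in the libraries at hand.

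Gene lists were compared with the other genes by Fisher's exact test, 2-sided, over 22481 genes annotated as protein-coding or named in a list, with Benjamini-Hochberg adjustment over the 12 lists within each line. A gene counted as holding an island when its body or the 1 kb upstream overlapped it. Where it overlapped several, the island of highest fold stood for the gene, so both lines can have islands at different places in a gene. A symbol with several annotation entries was counted once, by its longest entry. Fisher's test treats genes as independent although neighbouring genes can share an island, and long genes hold islands more often. The lists were therefore also tested against 10000 draws of genes matched over 20 classes of length and against 1000 circular shifts of the islands. A draw matched on length and on whether a gene lay on chromosomes 1, 8, 11 or 14 was added later. The lists covered pluripotency, trophoblast, housekeeping, promoters with textbook G-quadruplexes, long neural genes at fragile sites, chromatin loops, the X inactivation centre, imprinting, Hox clusters, feeder fibroblasts, histones (most of them replication-dependent), and olfactory and vomeronasal receptors. The histone and receptor lists were taken by symbol prefix. Older symbols were matched through a RefSeq table of GRCm38.p6, used for names only. The names Imm2l, Naaladl2, Cnbp2, Xite and Kcnq1ot1 found no matching entry in the annotation and were left out, and the open-ended prefix for newer olfactory symbols was not used.

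Sequence content was added after the data were examined. It was measured in 100-bp bins of the reference as the share of bins whose first 24-mer occurs 100 times or more in the genome. Per Mb of island, it counted G-quadruplex motifs (4 runs of 3 G with loops of up to 7 bases), runs of A or T of 15 bases or more, CA repeats of 10 units or more, and 4 or more joined telomere units. LINE-1 elements were counted through sites that encode a conserved stretch of the reverse transcriptase of their open reading frame 2. For each line 19 features were tested per list.

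The tests, the 12 gene lists and the naming rule were fixed before the data were examined. So was the choice of the lists with the 200 bp window and without unique mapping as the main ones. The rule named, per line, the 10 islands of highest fold with at least 50 ssDNA-seq reads and an FDR of 0.01 or less on chromosomes 1 to 19 or X, the widest island, and the highest island on Y. It also named the 10 shared pairs with the highest lower fold, the 5 pairs per direction with the largest ratio of folds, up to 4 members per gene list with islands in both lines, and Cdx2. No island lay on mitochondrial DNA. The other settings tried were unique mapping, an FDR of 1e-05 or less, a fold of 4 or more, at least 50 ssDNA-seq reads, an overlap of 50%, equal list sizes, the smaller window, other distances, a wider promoter and matched gene length. A fold of 2 or more, leaving out chromosomes 1, 8, 11 and 14, chromosomes 1, 8 and 11 alone, islands up to 400 bp, an overlap of 50% or 80% of both islands, strong islands against the whole unique-mapping list and shifts for gene lists were added later. For chromosomes 1, 8 and 11 a test on median folds was dropped, since islands are picked by calling. It was replaced by input density at equal fold with 4 classes of fold, then also with 10, 20 and 40 and with the error of the other autosomes, each after the values before it were seen.

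The statistics were tested on simulated data built from the TT2 ES islands. Of 20 randomly placed lists of 8722 islands, 0 gave an overlap p under 0.05, and all 5 lists with a planted overlap of 20% were found. For promoters, 2 of 10 random lists gave a p under 0.05 at ratios from 0.965 to 1.06, so a promoter ratio this near to 1 was not read as a difference. Lists with 500 islands planted at promoters were found in 3 of 3 cases. For the difference between lines, 198 of 200 pairs with a planted 4-fold ratio were called, none the wrong way, as were 2 of 2286 pairs with no planted change, and the intervals covered the true ratio in 94.9% of pairs. All planted changes were higher in TT2 ES. Only counting noise was simulated, so calls that arise from unequal widths of paired islands were not tested. For clustering, 0 of 20 random lists passed. They were placed in the same way as the random placements of the test, so this checked the computation only. No random list was built with clustered islands like those of the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used.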

Results

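The series mapped DNA that was single-stranded in living mouse ES cells, with ssDNA-seq in 2 lines and an input library for each. The Cdx2 ES line carries a doxycycline-regulated copy of Cdx2, the homeobox factor that directs the trophoblast fate, and TT2 ES is a wild-type line. Whether that copy was on or off in these cells is not given in the sources used here. Each group held 1 library, so no replicate spread exists, and all intervals given are 95% counting intervals. The values are the authors' islands of ssDNA-seq reads over input, on the mm9 build, with the read counts, FDR and fold of each island.

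Islands were many and short in the Cdx2 ES list and fewer, wider and weaker in the TT2 ES list. The Cdx2 ES list held 33025 islands over 99.3 Mb, with a median width of 2600 bp and a median fold over input of 1.73. The TT2 ES list held 8774 islands over 68.3 Mb, with a median width of 5200 bp and a median fold of 1.24. A fold of 2 or more was reached by 10387 Cdx2 ES islands (31.5%) and by 133 TT2 ES islands (1.52%), and a fold of 4 or more by 1074 and 7. The numbers of islands were not compared by a test, since each list came from 1 library with its own depth and its own input. The TT2 ES values rest mostly on chromosomes 1, 8 and 11, which held 84.4% of its islands. Median folds were 1.21 to 1.23 there and 1.34 to 1.45 on the other autosomes.

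The 10 Cdx2 ES islands ranked first by the authors' fold were all 200 bp wide and lay in introns or between genes. Among those with no input read, the island with most ssDNA-seq reads lay on chromosome 1 at 175766401 to 175766600. It lay between genes, 20752 bp from Mndal, with 84 ssDNA-seq reads, 14.2-fold over input at the floor (lower limit 11.3). Others with 0 input reads lay in introns of Gm609 (chromosome 16, 45466401 to 45466600), of Senp2, which encodes a SUMO protease (chromosome 16, 22042401 to 22042600), and of Cdk14, a cyclin-dependent kinase (chromosome 5, 4818201 to 4818400). Further such islands lay in introns of Gabrb1, a GABA-A receptor subunit (chromosome 5, 72143401 to 72143600), and of Galntl6 and the overlapping Gm17517 (chromosome 8, 60761401 to 60761600). The remaining 2 lay between genes, 228278 bp from Dcc on chromosome 18 (72739001 to 72739200) and 195961 bp from Olfm3 on chromosome 3 (115024601 to 115024800). Over these 8 islands the fold at the floor was 10.2 to 14.2, with lower limits of 8.03 to 11.3. The other 2 of the 10 held 1 input read each, 880525 bp from Gm9966 on chromosome 7 (102226001 to 102226200, fold 57.0, interval 10.02 to 2271) and 6123 bp from Tra2b on chromosome 16 (22272201 to 22272400, fold 44.8, 7.83 to 1789).

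The 10 TT2 ES islands ranked first by the authors' fold also lay mostly between genes. One lay on chromosome 17 at 20777001 to 20777200, 15160 bp from Fpr-rs3, with 72 ssDNA-seq reads and 0 input reads. Its fold at the floor was 6.72 (lower limit 5.32), so its place among the others is not known. The highest of those with input reads were on chromosome 12 at 98299801 to 98300000 (fold 12.7, 3.43 to 107), chromosome 1 at 50270601 to 50270800 (9.52, 2.54 to 80.2) and chromosome 1 at 196021401 to 196023000 (5.63, 2.901 to 12.5). Chromosome X held an island at 53252601 to 53253000 with a fold of 5.09 (2.71 to 10.8). An island at 74648601 to 74649800 on chromosome 15 covered the promoters and untranslated regions of Gml and Hemt1, with a fold of 3.94 (2.14 to 8.07). An island in an intron of Ankrd12 (chromosome 17, 66358401 to 66360600) had a fold of 3.79 (2.31 to 6.61). Another lay 1646 bp from Bhmt, which encodes a methyltransferase of methionine synthesis, with a fold of 4.01 (1.77 to 11.2; chromosome 13, 94384801 to 94385200). The last 2 of the 10 lay 23592 bp from Apba2 on chromosome 7 (71622401 to 71623000, fold 4.57) and 51453 bp from 6430527G18Rik on chromosome 12 (88169801 to 88170200, fold 3.44).

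The widest islands had folds near 1. In Cdx2 ES the widest ran over 176400 bp of chromosome 17 (30584601 to 30761000), across Btbd9 and the glyoxalase gene Glo1, with a fold of 1.03 (1.01 to 1.05) and 78.2 input reads per kb against a median of 35.5 over all islands. In TT2 ES the widest ran over 107600 bp of chromosome 11 (69441201 to 69548800), with a fold of 1.09 (1.05 to 1.14). It covered Fxr2, Sox15, Eif4a1, Senp3 and Polr2a, the gene of the largest subunit of RNA polymerase II. On chromosome Y both lines had their highest fold at the same 200 bp (2652201 to 2652400), 3.68 (2.42 to 5.84) in Cdx2 ES and 2.72 (1.25 to 7.02) in TT2 ES.

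TT2 ES islands were concentrated on chromosomes 1, 8 and 11. These chromosomes held 7405 islands, 84.4% of the list (83.6 to 85.2%), on 17.0% of the sequence. Their densities were 15.3 to 17.7 islands per Mb, against 0.288 to 1.195 on the 16 other autosomes. Their islands also held more input reads, 21.4 to 22.8 per kb against 17.3 to 19.1, and had lower median folds, 1.21 to 1.23 against 1.34 to 1.45. In Cdx2 ES chromosomes 11 and 14 stood apart in the same way, with 27.7 and 17.6 islands per Mb against 10.3 to 15.0 on the 17 other autosomes. Their islands held 39.1 to 41.8 input reads per kb against 31.1 to 36.3, at median folds of 1.42 to 1.57 against 1.68 to 1.94. Of the 133 TT2 ES islands of fold 2 or more, 40 (30.1%) lay on chromosomes 1, 8 and 11. These chromosomes were singled out after their values were seen.

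**Figure D1:**
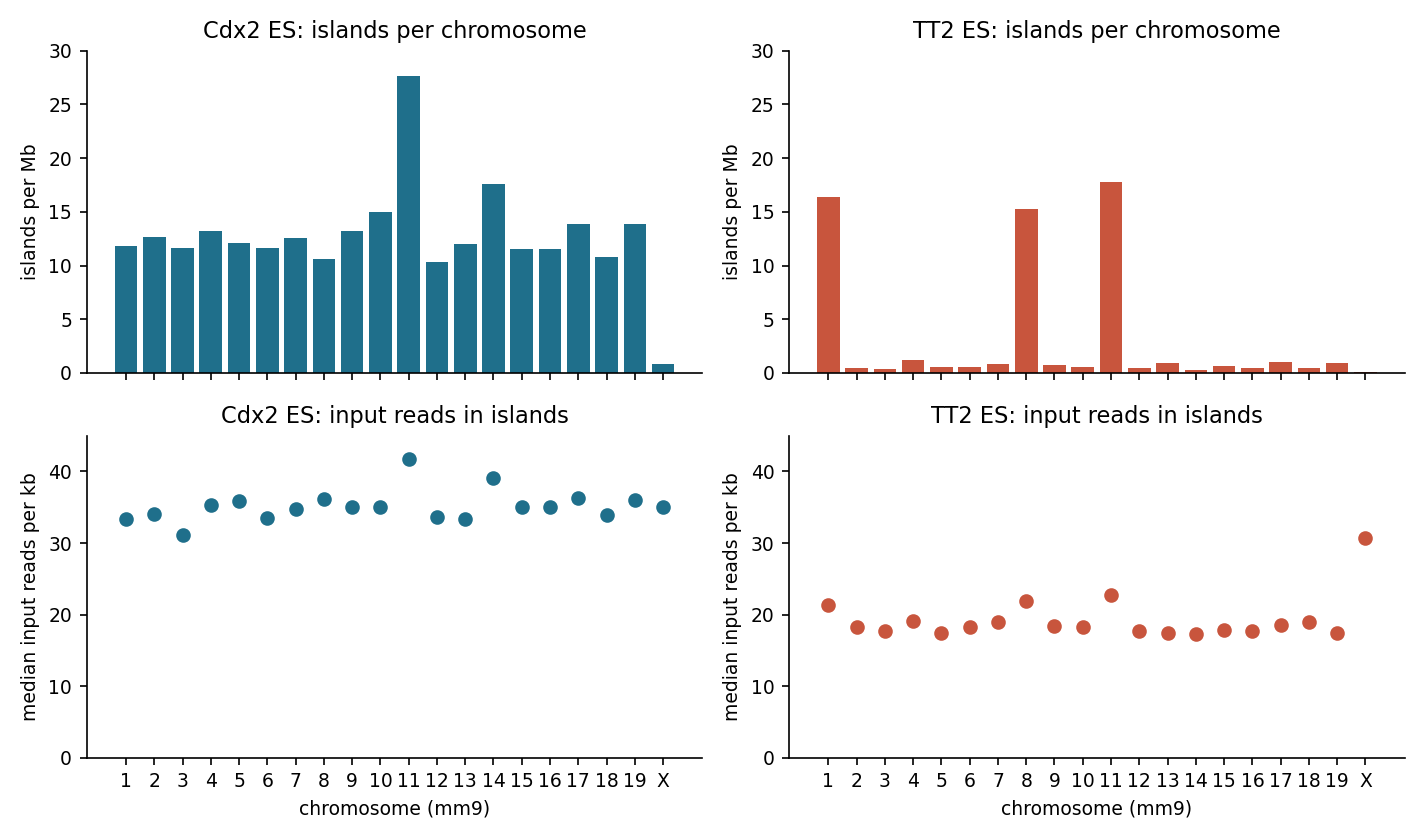
Bars give the number of islands per Mb of each chromosome and points the median number of input reads per kb of island, for Cdx2 ES (left) and TT2 ES (right). In TT2 ES chromosomes 1, 8 and 11 reach 15.3 to 17.7 islands per Mb while the other autosomes stay at or below 1.195, and in both lines the autosomes with most islands also hold most input reads in them.

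Chromosome X held few islands in both lines. Cdx2 ES had 133 islands on X, 0.798 per Mb, below all autosomes (10.3 to 27.7 per Mb, median 12.1), a ratio of 0.0657 to the median. The ratio was 0.0323 with unique mapping, 0.106 at a fold of 2 or more and 0.488 at 4 or more, with X below all autosomes each time. TT2 ES had 20, 0.120 per Mb, below all autosomes too (median 0.676, lowest 0.288), a ratio of 0.177 (0.0418 with unique mapping, 0.116 by covered bases). Among TT2 ES islands of fold 2 or more, X held 6, 0.0360 per Mb, and was within the range of the autosomes (0.0102 to 0.122), at 0.897 of their median. X is expected at 1 copy in male cells, and the sex of either line is not given in the sources used here.

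Islands of both lines lay at the same places more often than chance placed them. Of the TT2 ES islands, 2563 (29.2%, 28.3 to 30.2%) shared at least 1 base with a Cdx2 ES island, against a mean of 14.6% over circular shifts, a ratio of 2.00 (1-sided permutation p = 0.000999, the smallest that 1000 shifts can give). On chromosomes other than 1, 8, 11 and 14 the share was 54.1% (721 of 1333) against 8.91%, a ratio of 6.07 with the same p. On chromosomes 1, 8 and 11 it was 24.7% against 15.7%, a ratio of 1.58. Among islands of fold 2 or more, 48 of 133 TT2 ES islands (36.1%) met a Cdx2 ES island of fold 2 or more, against 1.82%. In the other direction 3463 Cdx2 ES islands (10.5%) met a TT2 ES island.

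The 10 shared pairs with the highest folds in both lines lay outside genes, and their positions are given as those of the Cdx2 ES island. Distances to genes are measured from the joint span of both islands of a pair. The highest, on chromosome 1 at 50270401 to 50270800, lay 686691 bp from Tmeff2 and had a fold of 9.52 (2.54 to 80.2) in TT2 ES and 34.8 (15.8 to 95.3) in Cdx2 ES. The pair on chromosome X at 53252601 to 53253200 had folds of 5.09 (2.71 to 10.8) and 14.5 (9.48 to 23.3), and that on chromosome 12 at 98299801 to 98300000 had 12.7 and 5.02. The pair on chromosome 17 near Fpr-rs3 had 6.72 at the floor (lower limit 5.32) in TT2 ES and 6.77 (4.13 to 11.8) in Cdx2 ES. Another pair lay 17390 bp from Foxd3, a forkhead factor of ES cells and neural crest (chromosome 4, 99304201 to 99305600), with folds of 2.74 and 2.59. A pair 1683 bp from Tceb3, the gene of elongin A (chromosome 4, 135556601 to 135557200), had folds of 2.65 and 3.17. The other 4 pairs lay on chromosomes 6 (67643001), 12 (88169801), 17 (83388201) and X (92128401), with TT2 ES folds of 2.82 to 3.44 and Cdx2 ES folds of 2.901 to 5.58.

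Folds of shared islands rose together in both lines. Over 2488 shared pairs, Spearman's rho of the log2 folds was 0.304 and Pearson's r 0.337 (permutation p = 1e-05 each, the smallest that 100000 resamples can give; across islands, which are not independent replicates). The median fold was 1.23 in TT2 ES and 1.55 in Cdx2 ES. In 44 pairs both folds were 2 or more, and 7 of these were at histone genes. The 18 pairs at histone genes had median folds of 1.85 in TT2 ES and 3.12 in Cdx2 ES, and the other 2470 had 1.23 and 1.54.

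**Figure D2:**
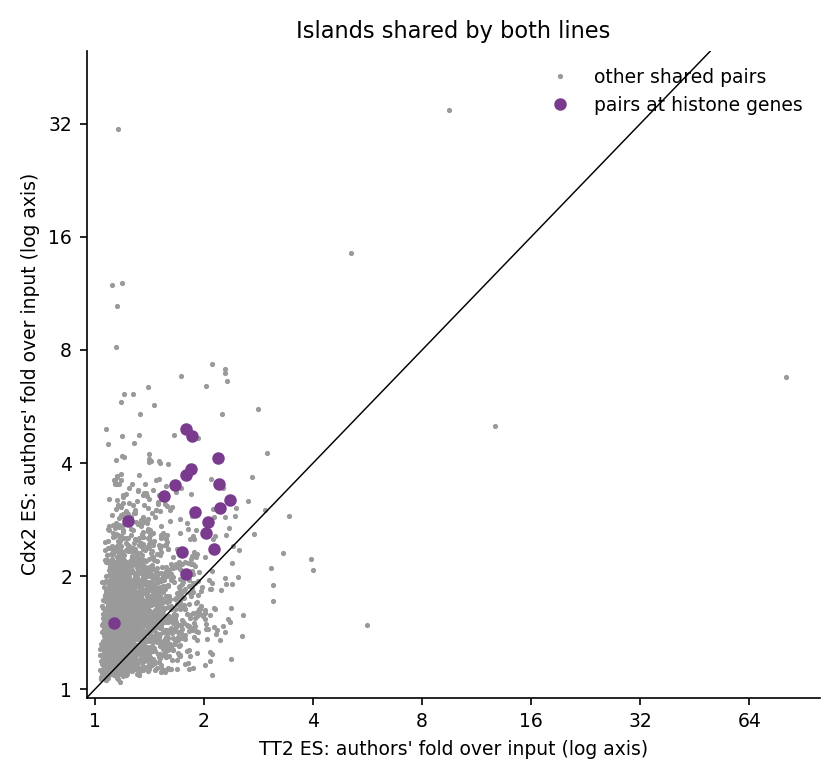
Each point is a pair of overlapping islands, with the authors' fold over input in TT2 ES on the horizontal log axis and in Cdx2 ES on the vertical log axis, and the line marks equal folds. Large points are the 18 pairs at histone genes, with Cdx2 ES folds from 1.502 to 4.93 and TT2 ES folds from 1.13 to 2.36.

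Shared islands with a large ratio of folds were mostly higher in Cdx2 ES, in part where a wide TT2 ES island was set against a narrow Cdx2 ES one. Of 2487 pairs with input reads in both lines, 166 had a fold at least 2 times higher in Cdx2 ES with an interval that excluded 1, and 1 was higher in TT2 ES. The median widths in these pairs were 3400 bp in Cdx2 ES and 6400 bp in TT2 ES, so the folds were averaged over unequal stretches. In 774 pairs that overlapped over 50% or more of both islands the counts were 24 and 1, and in 174 pairs at 80% or more they were 4 and 1. The pair higher in TT2 ES lay on chromosome 1 at 196021401 to 196023000, 423023 bp from Plxna2, where the TT2 ES fold of 5.63 was 3.79 times that of Cdx2 ES (interval 1.84 to 7.81). The next TT2 ES ratios were 1.97 (1.26 to 3.08) on chromosome X at 123299801 to 123301400, and 1.93 (1.48 to 2.52) at the promoter and exons of Ints6, a subunit of the Integrator complex (chromosome 14, 63376801 to 63383000). A coding exon of Pigk, of the complex that attaches GPI anchors, followed with 1.81 (1.05 to 3.10; chromosome 3, 152384201 to 152386000). The last of these 5 lay 10530 bp from X99384 on chromosome 10 (60856801 to 60860200), at 1.75 (1.19 to 2.57). The largest Cdx2 ES ratio, 26.8 (3.71 to 194), lay in an intron of the protocadherin gene Fat1 (chromosome 8, 46052601 to 46052800). Ratios of 7.11 to 10.7 followed at Gpr1, Nbeal1, Rasal2 and Rab3gap1, all on chromosome 1. In each of these 5 pairs a short Cdx2 ES island lay inside a much wider TT2 ES island. The median ratio of TT2 ES to Cdx2 ES was 0.826 (-0.27 on the log2 scale), and it was 0.859 and 0.838 at an overlap of 50% and 80% of both islands. After centring, which leaves the unequal widths as they were, 77 pairs were higher in Cdx2 ES and 10 in TT2 ES.

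A part of the islands was lost from the unique-mapping lists. With unique mapping, 72.7% of Cdx2 ES islands (72.2 to 73.2%) and 86.9% of TT2 ES islands (86.2 to 87.6%) still met an island. Of Cdx2 ES islands of fold 4 or more, 570 of 1074 did (53.1%, 50.0365 to 56.1%), and 353 (32.9%, 30.1 to 35.8%) met one that itself had a fold of 4 or more. In TT2 ES 2 of 7 did, and the island on chromosome 1 at 196021401 met one of fold 4 or more. Lost Cdx2 ES islands were narrower than kept ones, with a median of 2000 against 2800 bp, at nearly equal median folds of 1.74 and 1.73. The unique-mapping lists were not subsets: 90.0% of the 26167 Cdx2 ES and 74.9% of the 10247 TT2 ES unique-mapping islands met an island of the main list. A lost island therefore need not have rested on reads with several places in the genome.

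Most Cdx2 ES islands held an island of the list with a smaller window. Of the 33025 islands, 30030 (90.9%, 90.6 to 91.2%) held an island of the list with a 100 bp window, with a median of 1 and at most 11 per island. That list had 67998 islands over 68.0 Mb with a median width of 800 bp, and 27633 of them lay outside the larger islands.

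Islands lay closer together than random placement put them. In Cdx2 ES 48.9% of islands had another within 10 kb, against 30.9% at random, and in TT2 ES 48.4% against 38.4% (1-sided permutation p = 0.000999 in each line). On chromosomes other than 1, 8, 11 and 14 the TT2 ES share was 23.9% against 2.83%.

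Promoters and exons held TT2 ES islands more often than chance placement did, and strong Cdx2 ES islands less often. In TT2 ES 20.7% of islands covered a promoter against 12.2% after shifts (ratio 1.70, 2-sided permutation p = 0.000999), and coding exons (33.9% against 22.2%) and untranslated regions (24.8% against 15.0%) were covered more often too. On chromosomes other than 1, 8, 11 and 14 promoters were covered by 33.7% of TT2 ES islands against 9.20%, a ratio of 3.67. In Cdx2 ES promoters were covered by 7.70% of islands against 7.29% (ratio 1.06, permutation p = 0.121). The promoter ratio was 1.15 with unique mapping and 1.15 with 2 kb to each side (permutation p = 0.000999 each). Coding exons were covered by 11.8% against 14.02% (permutation p = 0.000999), a call lost with unique mapping (15.2% against 15.9%, permutation p = 0.0819). Cdx2 ES islands of fold 2 or more avoided genes: 2.67% covered a promoter against 5.61%, and 2.73% a coding exon against 10.4%, while 68.4% covered intergenic sequence against 59.99% (permutation p = 0.000999 each). TT2 ES islands of fold 2 or more covered promoters in 24.1% against 6.45%. GC content was 41.9% in Cdx2 ES islands and 42.4% in TT2 ES islands, against 42.1% and 42.4% after shifts (permutation p = 0.0819 and 0.880). In Cdx2 ES it was 40.7% against 41.9% at a fold of 2 or more and 43.2% against 41.8% at 4 or more (permutation p = 0.000999 each), and in TT2 ES without chromosomes 1, 8, 11 and 14 it was 43.4% against 42.1% (permutation p = 0.00699). Whether the lines differed in these shares was not tested.

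Repeated sequence filled much of the Cdx2 ES islands. High-copy 24-mers, which occur 100 times or more in the genome, began 29.6% of the bins in Cdx2 ES islands against 9.42% after shifts. At a fold of 2 or more the share was 42.1% against 9.65%. At a fold of 4 or more the ratio was 4.22. In TT2 ES such 24-mers began 6.42% of the bins against 9.07%, but 9.21% against 9.76% at a fold of 2 or more (permutation p = 0.779). LINE-1 reverse transcriptase sites were 4.68 times as dense in Cdx2 ES islands as after shifts (34.2 against 7.31 per Mb) and 6.22 times at a fold of 2 or more, but 0.695 times at a fold of 4 or more (permutation p = 0.444). In TT2 ES they were less dense, 2.87 against 6.93 per Mb. LINE-1 elements are retrotransposons that encode their own reverse transcriptase, and 3311 Cdx2 ES islands (10.1%) held such a site against 192 in TT2 ES (2.20%). G-quadruplex motifs, guanine runs that can fold into 4-stranded DNA, were 1.04 times as dense in Cdx2 ES islands as after shifts, 1.36 times at a fold of 2 or more and 2.62 times at 4 or more. They were 0.876 times as dense in TT2 ES, a call lost without chromosomes 1, 8, 11 and 14 (0.940, permutation p = 0.216). With unique mapping the Cdx2 ES ratio over all islands was 0.980. CA repeats were rarer, at 0.530 times in Cdx2 ES and 0.886 times in TT2 ES, and runs of A or T were denser, at 1.52 and 1.29 times. These sequence features were chosen after the data were examined, and each ratio without a p here had a permutation p = 0.000999, except with unique mapping (permutation p = 0.0869).

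**Figure D3:**
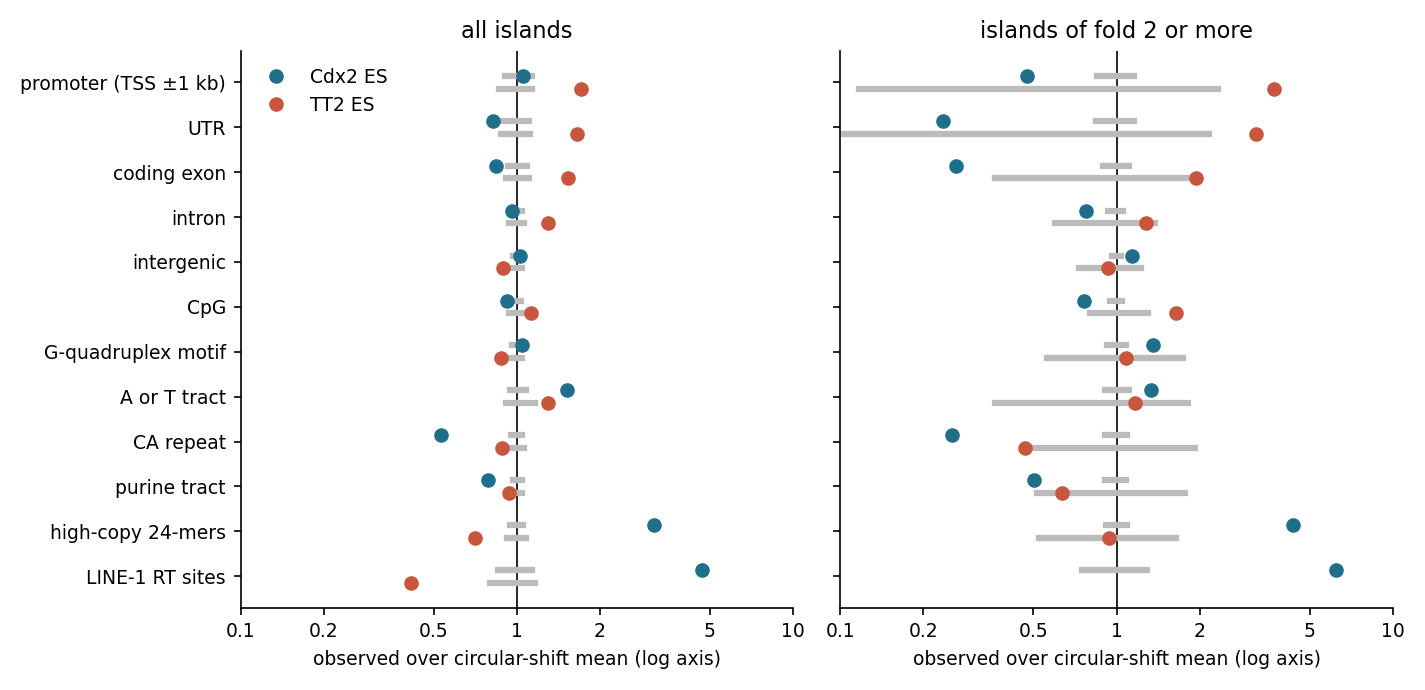
Points give the share or density of each feature in islands divided by its mean over circular shifts, on a log axis, for all islands (left) and islands of fold 2 or more (right), and grey bars span the lowest to the highest shift, with the lower end set at the axis limit where it falls below. High-copy 24-mers reach 3.14 in Cdx2 ES and 0.708 in TT2 ES, and promoters 1.06 and 1.70. TT2 ES islands of fold 2 or more held no LINE-1 site and have no point there.

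Histone genes, most of them replication-dependent and transcribed in S phase for new chromatin, held islands in both lines far more often than other genes. Taken by symbol prefix, they included the linker histone genes H1fx, H1foo, H1f0 and H1fnt, which are not replication-dependent and held no island in either line, and the pseudogene Hist3h2bb-ps. Islands lay at 57 of 73 genes of the list in Cdx2 ES (78.1% against 30.7% of other genes, odds ratio 8.05, Fisher's exact adjusted p = 6.42e-16). In TT2 ES they lay at 43 of 73 (58.9% against 13.4%, odds ratio 9.25, Fisher's exact adjusted p = 9.45e-19). Both lines had an island at 39 of them, with median folds of 2.97 and 1.86, and at 15 both folds were 2 or more. The linker histone gene Hist1h1a (chromosome 13, 23855537 to 23856283) had folds of 4.93 (4.06 to 6.03) in Cdx2 ES and 2.33 (1.70 to 3.24) in TT2 ES. Its neighbours Hist1h3a and Hist1h4a shared that Cdx2 ES island and had 1.79 (1.27 to 2.59) in TT2 ES. Hist2h2bb on chromosome 3 (96073644 to 96082924) had folds of 4.73 (3.37 to 6.83) and 1.86 (1.39 to 2.52). Since neighbours share islands, the 57 genes stood on 35 islands and the 43 on 20. Against circular shifts, which keep neighbours together, 5.08 and 1.15 such genes were met by chance (permutation adjusted p = 0.00599 and 0.00300).

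**Figure D4:**
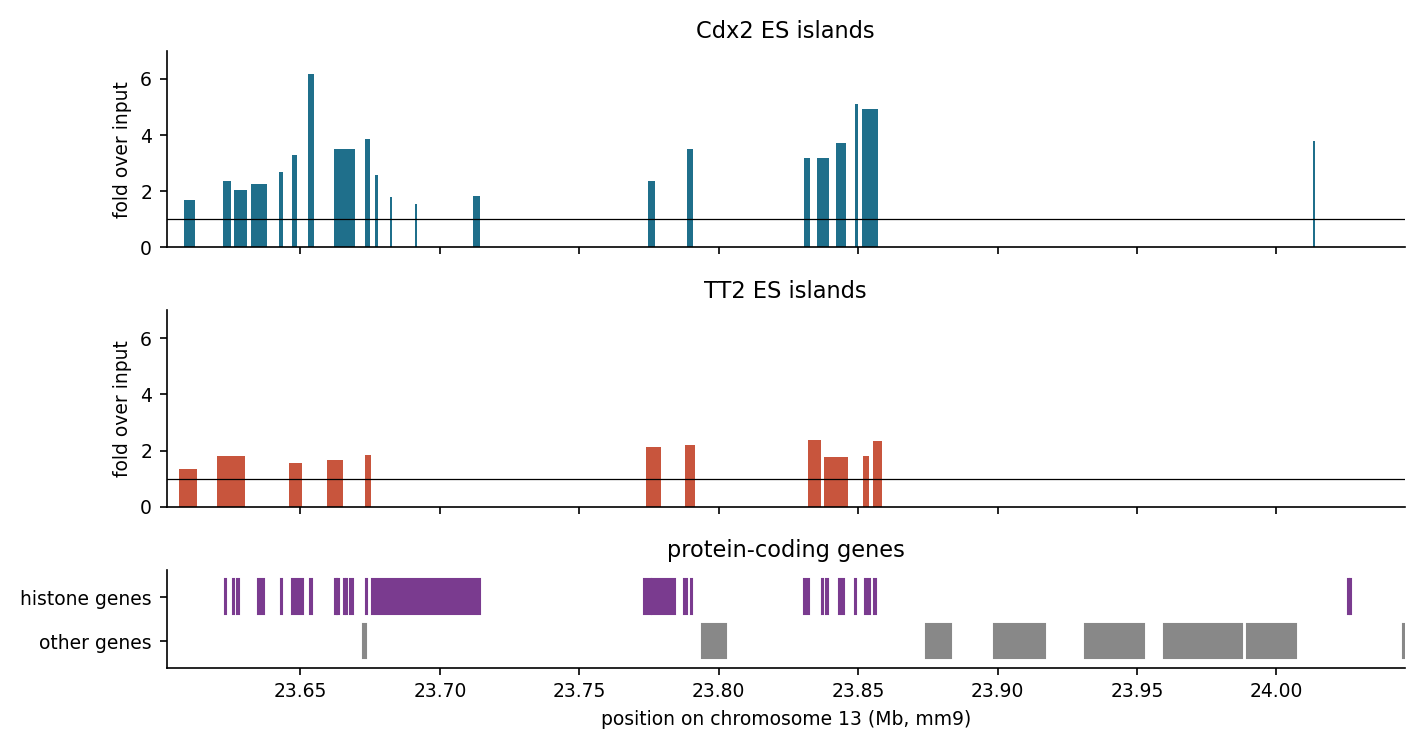
Islands of Cdx2 ES and TT2 ES over 23602001 to 24046000 of chromosome 13 (mm9), drawn to scale with the authors' fold as bar height and the level of 1 as a line, above the protein-coding genes. Of 21 Cdx2 ES islands 19 overlap 1 or more of the histone genes, as do 10 of 11 TT2 ES islands, at folds of up to 6.19 and 2.36. Hist1h2be is drawn by its longest entry (23675611 to 23712993). The Cdx2 ES islands that start at 23676601, 23682001 and 23691201 lie inside that entry and overlap no other histone gene.

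Highly expressed housekeeping genes held islands in both lines as well, at 26 of 30 in Cdx2 ES and 20 of 30 in TT2 ES (odds ratios 14.6 and 12.8, Fisher's exact adjusted p = 1.34e-09 and 1.28e-10), and 19 in both. Hnrnpa2b1, an RNA-binding protein gene on chromosome 6 (51410433 to 51419893), had folds of 3.16 (2.57 to 3.92) in Cdx2 ES and 1.49 (1.32 to 1.69) in TT2 ES. The Y-box factor Ybx1 had 2.38 and 1.53, the chaperone Hspa8 2.26 and 1.88, and the pyruvate kinase Pkm2 1.33 and 2.12. At a fold of 2 or more the Cdx2 ES count was 6 of 30 (odds ratio 2.26, Fisher's exact adjusted p = 0.276), and at 4 or more it was 0. The TT2 ES count at a fold of 2 or more was 2 of 30 (odds ratio 17.7, Fisher's exact adjusted p = 0.0268). Of the pluripotency genes, 8 of 25 held an island in TT2 ES (odds ratio 3.004, Fisher's exact adjusted p = 0.0432; 0.105 with unique mapping). The TT2 ES permutation adjusted p was 0.00300 against circular shifts and 0.0216 among genes of equal length. In Cdx2 ES 10 of 25 held one (odds ratio 1.497, Fisher's exact adjusted p = 0.463; permutation adjusted p = 0.0300 against circular shifts and 0.151 among genes of equal length). The TT2 ES folds were low, at 1.11 for the homeobox gene Nanog, 1.13 for the 5-methylcytosine dioxygenase Tet1, 1.33 for Dnmt3l and 1.32 for Dppa3. Their Cdx2 ES folds were 1.60, 1.63, 1.48 and 1.09. None of the 25 held an island of fold 2 or more in either line.

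Long neural genes at fragile sites held Cdx2 ES islands in 20 of 24 cases (odds ratio 11.3, Fisher's exact adjusted p = 4.69e-07), but their count did not pass against other genes of their length (ratio 1.17, permutation adjusted p = 0.303). At a fold of 2 or more it was 20 of 24 (odds ratio 45.5, Fisher's exact adjusted p = 2.55e-16) and at 4 or more 7 of 24 (odds ratio 24.4, Fisher's exact adjusted p = 5.94e-07), not matched on length. Circular shifts met 23.2 of these genes on average, so the Cdx2 ES count was lower than chance placement gave (ratio 0.863, permutation adjusted p = 0.00599). In TT2 ES the count was 3 against 9.71 after shifts (permutation adjusted p = 0.00300; Fisher's exact adjusted p = 1.0). Csmd1 on chromosome 8 had folds of 3.38 (2.15 to 5.56) and 1.66 (1.24 to 2.28), and the polarity gene Pard3b 2.51 and 1.83. Genes of chromatin loops and the nuclear matrix held Cdx2 ES islands in 13 of 18 cases (odds ratio 5.84, Fisher's exact adjusted p = 7.22e-04), a call lost among genes of equal length (permutation adjusted p = 0.151) and at a fold of 2 or more (2 of 18, Fisher's exact adjusted p = 0.833), but kept against circular shifts (ratio 1.80, permutation adjusted p = 0.00599). In TT2 ES 6 of 18 did (Fisher's exact adjusted p = 0.0644), a call gained with unique mapping (9 of 18, Fisher's exact adjusted p = 0.00174) and against circular shifts (ratio 2.20, permutation adjusted p = 0.0432) but not among genes of equal length (ratio 1.73, permutation adjusted p = 0.333). The nuclear matrix gene Matr3 had folds of 1.55 (1.37 to 1.75) in Cdx2 ES and 2.997 (2.11 to 4.39) in TT2 ES. The insulator gene Ctcf had 1.97 and 1.24, the cohesin gene Smc3 1.92 and 1.31, and the scaffold gene Hnrnpu 1.46 and 1.296.

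Olfactory and vomeronasal receptor genes, silent in most tissues, held few islands, at 95 of 1682 in Cdx2 ES and 26 in TT2 ES (odds ratios 0.122 and 0.0923, Fisher's exact adjusted p = 2.64e-153 and 4.13e-73). Against circular shifts the Cdx2 ES ratio was 0.605 (permutation adjusted p = 0.0120) and the TT2 ES ratio 0.643 (permutation adjusted p = 0.307). Among genes of equal length the ratios were 0.735 and 0.320 (permutation adjusted p = 8.00e-04 and 4.00e-04). The receptor genes with islands in both lines lay on chromosome 11, and the 4 highest Cdx2 ES folds among them were 2.89 for Olfr1373, 2.07 for Olfr56, 1.84 for Olfr75-ps1 and 1.54 for Olfr1382, with 1.104 to 1.51 in TT2 ES. Hox genes, the developmental regulators along the body axis, held islands at 0 of 39 in Cdx2 ES (Fisher's exact adjusted p = 1.75e-06; 0.137 against circular shifts) and at 6 in TT2 ES (adjusted p = 0.859). The 6 were Hoxb1, Hoxb4, Hoxb5, Hoxb6, Hoxb7 and Hoxb8, all on chromosome 11.

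The other lists did not pass Fisher's exact test in either line. Trophoblast genes held islands at 4 of 25 in Cdx2 ES and 2 in TT2 ES, with Tead4, a factor of the trophectoderm, at folds of 1.28 and 1.33. Genes with textbook G-quadruplex promoters had 5 and 2 of 15, with the p53 ligase gene Mdm2 at 2.42 and 1.45 and the survival gene Bcl2 at 1.27 and 1.52. Imprinted genes had 5 and 2 of 29, with Grb10 at 2.24 and 1.18. Feeder fibroblast genes had 4 and 3 of 19, with fibronectin (Fn1) at 3.69 and 1.32 and collagen (Col1a1) at 1.11 and 1.25. The X inactivation centre had 1 and 0 of 9. Cdx2 itself, on chromosome 5 (148112381 to 148118846), held no island in either line. Measured from the gene with its 1 kb upstream, the nearest lay 27.2 kb away in Cdx2 ES (148147001 to 148150800, fold 1.42) and 1467 kb away in TT2 ES.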

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

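The tests on chromosomes, on low input at histone genes, on LINE-1 in islands of fold 4 or more and on reads with several places in high-copy sequence were chosen only after the results were seen, and the others were written down before their values were computed.

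High-copy sequence was singled out because the lines moved in opposite directions. The density of 24-mers with 100 or more copies over circular shifts was 3.14 in Cdx2 ES and 0.708 in TT2 ES. The difference between the lines was not tested, and each line had 1 library. Islands on unplaced or unlocalised sequences, which the comparisons leave out, numbered 105 in Cdx2 ES and 52 in TT2 ES.

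The high-copy sequence in Cdx2 ES islands could come from LINE-1 elements or from reads with several places. LINE-1 reverse transcriptase sites were 6.22 times as dense in islands of fold 2 or more as after shifts, which fits copies of their open reading frame 2 there. At a fold of 4 or more the high-copy ratio was 4.22 but that of LINE-1 sites 0.695 (permutation p = 0.444), so LINE-1 stays open for the strongest islands. With unique mapping the high-copy ratio was 2.61, so reads with several places may add to it but are excluded as the whole cause. Whether LINE-1 DNA itself was single-stranded, or was recovered more efficiently, could not be separated with 1 library.

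The TT2 ES islands on chromosomes 1, 8 and 11 could come from a gain of these chromosomes in the cells. The lowest median input density there was 21.4 reads per kb, above the highest of the other autosomes, 19.1, which fits a gain that lets weak enrichment pass the island caller. More single-stranded DNA at unchanged copy number stays open. At equal fold the lowest input on these chromosomes was above the highest of the other autosomes in each setting. It was 1.08 against 1.02 times with 4 classes of fold and 1.07 against 1.03 with 10. With 20 it was 1.04 (1.03 to 1.06) against 1.03, and with 40 it was 1.06 against 1.02. Only with 4 classes did its lower limit, 1.07276, pass the highest upper limit of the other autosomes, 1.07197. With 10, 20 and 40 it lay within their error. Reads with several places may be set aside, since unique mapping left 82.5% of islands there against 84.4%. Chromosome X held 30.7 input reads per kb in its 20 islands, more than these chromosomes, at only 0.120 islands per Mb. Input density in islands thus need not follow their number. Input density was read inside called islands only, so copy number itself was not measured.

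The islands at histone genes could come from copy gain, shared reads, low input or open DNA at these genes. The input density at the 39 genes with islands in both lines was 0.881 and 0.838 times that of their chromosome in the 2 lines, which gave no sign of a gain. The island of highest fold stood for each gene, which favours low input, and no comparison at equal fold was made. A gain is therefore not excluded. Unique mapping kept an island at 94.9% and 100% of them, so shared reads were not the whole cause at most of these genes. The kept island could be a different one and its fold was not compared, so such reads may add to the folds. With the input density of the chromosome in place of their own, the median fold was 1.06 times that of the chromosome in TT2 ES and 1.37 times in Cdx2 ES. That chromosome fold kept each island's own input, so the small TT2 ES lead cannot decide whether low input is the whole cause there. By this measure low input was not the whole cause in Cdx2 ES. In TT2 ES it could account for much of the lead, where the median fold fell from 1.86 to 1.53.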

How the results depend on the processing

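A fold of 2 or more, chromosomes 1, 8 and 11 alone, leaving out chromosomes 1, 8, 11 and 14, an overlap of both islands, strong islands against the whole unique-mapping list, sequence content, and, for gene lists, circular shifts and matching on length and chromosome group were chosen only after the results were seen. Of 180 alternatives over 35 results, 117 kept the main reading, 28 moved a value, 18 were weaker, 4 stronger and 13 reversed. For tests the main reading was the direction and side of the threshold. For counts and shares it was a value near the main one, and for X its place below all autosomes.

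Island counts in Cdx2 ES were 10387 at a fold of 2 or more, 1074 at 4 or more and 67998 with the smaller window. In TT2 ES they were 133, 7, 4734 at the lower FDR and 1333 without the 4 chromosomes. The X ratio in TT2 ES was 0.897 at a fold of 2 or more, and at 4 or more it had no value, since the autosome median was 0. Pairs higher in Cdx2 ES and TT2 ES numbered 95 and 3 with unique mapping, 77 and 10 after centring, 12 and 0 at a threshold of 4, 46 and 0 without the 4 chromosomes, and 24 and 1, and 4 and 1, with an overlap of 50% and 80% of both islands. At a fold of 4 or more and at the lower FDR, 53.1% and 74.8% of Cdx2 ES islands met the whole unique-mapping list, and 32.9% and 71.4% met it with the same filter on both lists. In TT2 ES these were 28.6% and 92.5%, and 14.3% and 84.7%. The smaller window gave 89.9% with an overlap of 50% and 84.5% at a fold of 4 or more.

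Promoter ratios in Cdx2 ES were 1.15 with 2 kb to each side, 1.15 with unique mapping, 0.476 at a fold of 2 or more and 0.544 at 4 or more. In Cdx2 ES at a fold of 4 or more, LINE-1 was 0.695 and GC content 1.04, and G-quadruplex motifs were 0.980 with unique mapping. In TT2 ES at a fold of 2 or more, high-copy 24-mers were 0.943 and G-quadruplex motifs 1.08. At 4 or more, with 7 islands left, clusters and promoters fell to 0, high-copy 24-mers rose to 6.32 and GC content was 0.986. The odds ratio of housekeeping genes in Cdx2 ES at a fold of 4 or more was 0, as was that of pluripotency genes in TT2 ES at 2 or more, and fragile-site genes in Cdx2 ES had 0.863 against circular shifts. Fewer islands remain under a stricter fold, and beyond that the cause was not tested. TT2 ES gene lists and telomere repeats at a fold of 4 or more gave no ratio. The minimum of 50 ssDNA-seq reads removed no island, since the lowest count in the main lists was 60. Its alternatives are counted among those that kept the main reading, although they could not have differed. No paired analysis was possible because each group had 1 library. Input depth, a median of 87 and 104 reads per island, limits the folds.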

Other observations

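The shared pairs in the first paragraph were chosen only after their values were seen, and the telomere test was written down before its value was computed. The pairs named here were picked from the next 50 shared pairs by lower fold after those named above. Many of the rest lay between genes. The Mir290 to Mir295 cluster, the main microRNA cluster of mouse ES cells, held an island in both lines (chromosome 7). In TT2 ES it ran over 3217001 to 3224000 with a fold of 2.12 (1.71 to 2.64). The Cdx2 ES fold was 2.52 (2.20 to 2.902). The joint span of this pair also covered a coding exon and untranslated sequence of Nlrp12. The U4 spliceosomal RNA genes on chromosome 5 had folds of 2.14 and 2.88, U5 on chromosome 4 had 3.06 and 2.10, and Snhg1, the host of several C/D box RNAs, had 1.90 and 2.66. The ribosomal protein gene Rps12, with Snora33 and Snord100, had 2.14 and 2.56, the chaperone gene Hspa5 2.298 and 1.91, and the heterochromatin protein gene Cbx3 2.49 and 2.35.

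Telomere-type repeats in narrow islands may come from reads of chromosome ends placed at internal repeats. Of islands of up to 400 bp, unique mapping lost 8 of 9 with such a repeat (88.9%, 51.8 to 99.7%) and 56.8% of 1485 without (Fisher's exact p = 0.0869), so the test left this open.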
